A study of Sus scrofa domesticus with 16 samples.

How the data were processed

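The deposited intensity values are linear MAS5 signals from the Affymetrix GeneChip Porcine Genome Array, made with Affymetrix Expression Console 1.1.1, per the submitters' processing notes; the version of MAS5 is not given in the sources used here. In each deposited column the mean intensity without the highest and lowest 2% of probe sets was 500, so each array had been scaled as a whole, and no quantile normalization between arrays was visible. The table had 1 column per animal, no column was left unused, and no 2 columns held identical values. The raw scans and detection calls were not used here.

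Values were taken to log2. Of the probe sets, 124 controls were set aside and 23999 kept. In the annotation used, 10069 of these had 1 gene symbol, 198 had several and 13732 had none. Of those with 1 symbol, 9961 matched an entry of the reference gene table (assembly Sscrofa11.1, used for names only) by gene number, and 0 symbols changed. Of 16 adrenal genes chosen for naming, 10 were measured and the others were not analysed here. Probe sets with a mean log2 signal under the 40th percentile (log2 6.15, a signal of 71.1) were left out, which kept 14399 probe sets, 7272 of them with 1 symbol, for 5455 genes.

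The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a constant prior variance, two-sided), with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of adjusted p under 0.05. Of 34 gene lists fixed before the data were examined, 31 with at least 3 measured genes were tested with camera at its preset correlation of 0.01, with the brightest probe set per gene and adjustment over the 31 lists. The skeletal muscle list (2 genes measured) and the kidney and liver list (0 genes) were not tested, and the sex-linked list served only as a covariate. Cell composition was compared through the mean log2 signal of 9 of 11 cell type lists with an exact permutation test over all 12870 splits, two-sided. The genes named are the 12 named probe sets with the smallest p in each direction, the measured genes among the 16, and the 2 to 4 with the smallest p in a list described; any other gene is said to have been chosen after its value was seen. The main design, the lists, the rule for named genes and most alternatives were fixed before the data were examined.

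The 2 spike-in sets were found in the data, by the signal of the dap control, so the fits with the set as a block or within a set, the actin covariate and the exact permutation of list means were added after the data were seen; within the sets there are 4900 exact splits. The alternatives chosen beforehand were no filter and a filter at the 60th percentile, quantile normalization, median centring, a pseudocount of 23.5 (the 20th percentile of signal), an intensity trend with a robust prior, array weights, and the first digit of the animal number as a block. To these came a medulla covariate, a Y-linked covariate, an estimated correlation, fry, the mean of a gene's probe sets, other thresholds and leaving out each animal in turn. Outlying animals were sought with Dixon's ratio (critical value 0.526 for 8 values). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

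The scripts were first run on simulated data for the high against low stress comparison, with the real means and spreads of 14399 probe sets, independent errors, and 5 simulations of 200 changed probe sets. Without a block, 28.7% of changes of log2 0.5, 81.5% of log2 1 and 96.7% of log2 1.5 were recovered, and 8 of 70995 unchanged probe sets were called. With the set as a block the shares were 47.2%, 91.9% and 98.8%, with 44 unchanged probe sets called. For the same comparison over 5455 genes, a simulated list of 11 genes shifted by log2 0.4 was called in 5 of 5 simulations by both fits, and 0 lists were called without a shift. Independent errors leave out the correlation between genes that the real arrays have.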

Results

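Gene expression was measured in the adrenal glands of 16 domestic pigs, with 1 porcine genome array per animal. Pigs unknown to each other had been mixed, and 8 animals labelled high stress, from a mixing treatment with high aggressiveness, were set against 8 labelled low stress. The submitters state that both groups were chosen to differ in fighting behaviour and in circulating cortisol, so the comparison asks how gene expression in the gland differed between animals chosen in that way. The adrenal gland has a cortex that makes steroid hormones such as cortisol and a medulla whose chromaffin cells make catecholamines. Each array gave an intensity for 23999 probe sets besides its controls, and the median signal of an array lay between 116 and 148. Across the probe sets tested, 2 animals of the low stress group correlated at 0.917 to 0.969 and 2 animals of the high stress group at 0.917 to 0.972. The log2 signal of a Y-linked probe set was 9.25 to 10.60 in low stress replicates 2, 3, 5 and 8 and in high stress replicates 2, 3, 6 and 8. It was at most 4.86 in the other animals, so both sexes were present in each stress group. The number of arrays limits the precision.

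The arrays fell into 2 sets of 8 that the labels do not mention. The signal of dap, a bacterial transcript added to the RNA as a labelling control, averaged 896 in the low-spike set and 4255 in the high-spike set, a 4.75-fold difference. Each set held 4 high stress and 4 low stress animals. The first principal component, with 37.5% of the variance, separated the sets (exact permutation p = 0.000155, the smallest these arrays allow, two-sided) and not the stress groups (exact permutation p = 0.567). Of 14399 probe sets, 5767 differed between the sets at an adjusted p under 0.05 with limma. The ratio of 3' to 5' signal, a measure of RNA length, averaged 13.6 in the low-spike set and 6.78 in the high-spike set for actin, but 1.38 and 1.51 for GAPDH, so the controls did not point the same way. The lists that passed are therefore given beside a fit with the set as a block and within each set, and single genes over all arrays unless stated.

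**Figure D1:**
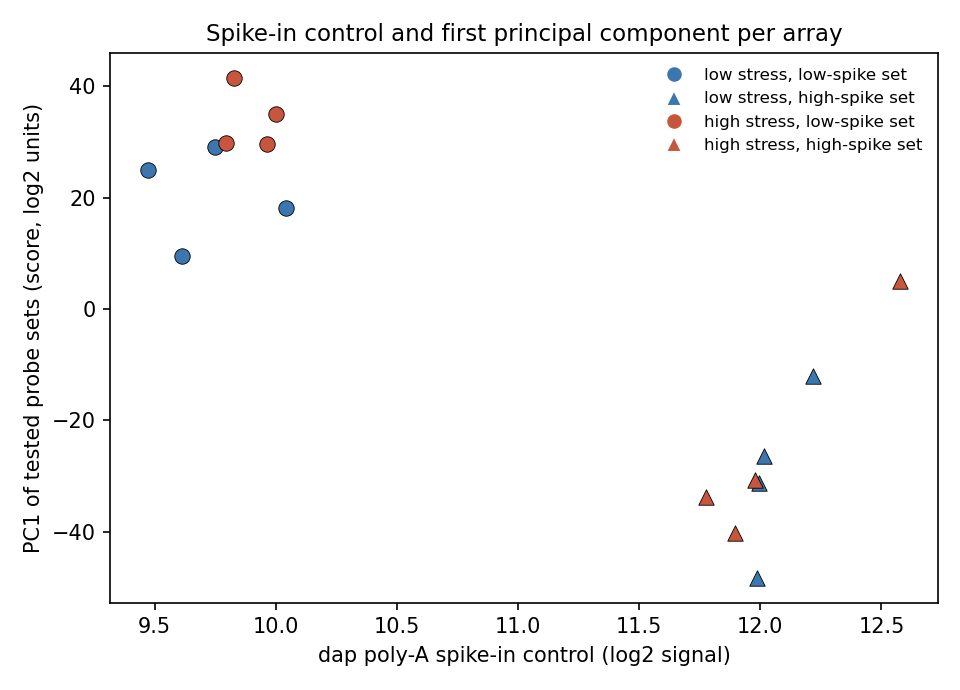
Each point is 1 array, placed by the log2 signal of the dap spike-in control and its score on the first principal component of the 14399 probe sets tested, with colour for the stress group and shape for the spike-in set. The 8 arrays between 9.47 and 10.04 on the control all have positive scores, and both stress groups lie in both sets.

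Genes of cholesterol synthesis, the pathway that builds the precursor of all adrenal steroids, had higher values in high stress glands in all 11 measured members, with a median log2 fold change of 0.40. The list passed camera at its preset correlation (adjusted p = 1.88e-09) but not otherwise (adjusted p = 0.389 with an estimated correlation), and none of the 11 genes passed over all genes. The list mean was 11.17 ± 0.33 on the log2 scale in high stress and 10.74 ± 0.28 in low stress (SD, n = 8 each). While 8 of 8 high stress animals lay above the low stress mean, the groups overlapped. High stress animals ranged from 10.80 to 11.80 and low stress animals from 10.16 to 11.02. The low stress mean was drawn down by its lowest animals, at 10.16 and 10.49. The other low stress animals, at 10.75 to 11.02, lay above that mean too. HSD17B7, which reduces a ketone of the sterol intermediates, was 2.11-fold higher (log2 fold change 1.08, SE 0.27). TM7SF2, a sterol reductase, was 1.51-fold higher (0.59, SE 0.23), FDPS, which makes farnesyl diphosphate, 1.43-fold (0.51, SE 0.21) and SQLE, the epoxidase that acts on squalene, 1.36-fold (0.45, SE 0.19).

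Camera, limma's test of a list against all other genes, was adjusted over 31 lists. With the set as a block the cholesterol synthesis list had an adjusted p of 4.90e-08 (adjusted p = 0.721 with an estimated correlation beside the block). The mean log2 fold change of the list was 0.44 within the low-spike set and 0.41 within the high-spike set. An exact two-sided permutation test of the list mean gave p = 0.00979, or 0.304 after Benjamini-Hochberg adjustment over the 31 lists, and p = 0.0159 when labels were exchanged only within the sets, or 0.228 adjusted. Adjusted over the list alone, HSD17B7 passed (adjusted p = 0.00881), and 7 genes passed with the block. HMGCS1, an early enzyme of the pathway, did not pass (log2 fold change 0.29, SE 0.17), nor did MSMO1 (0.08, SE 0.21), named here after its value was seen as the smallest of the list.

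**Figure D2:**
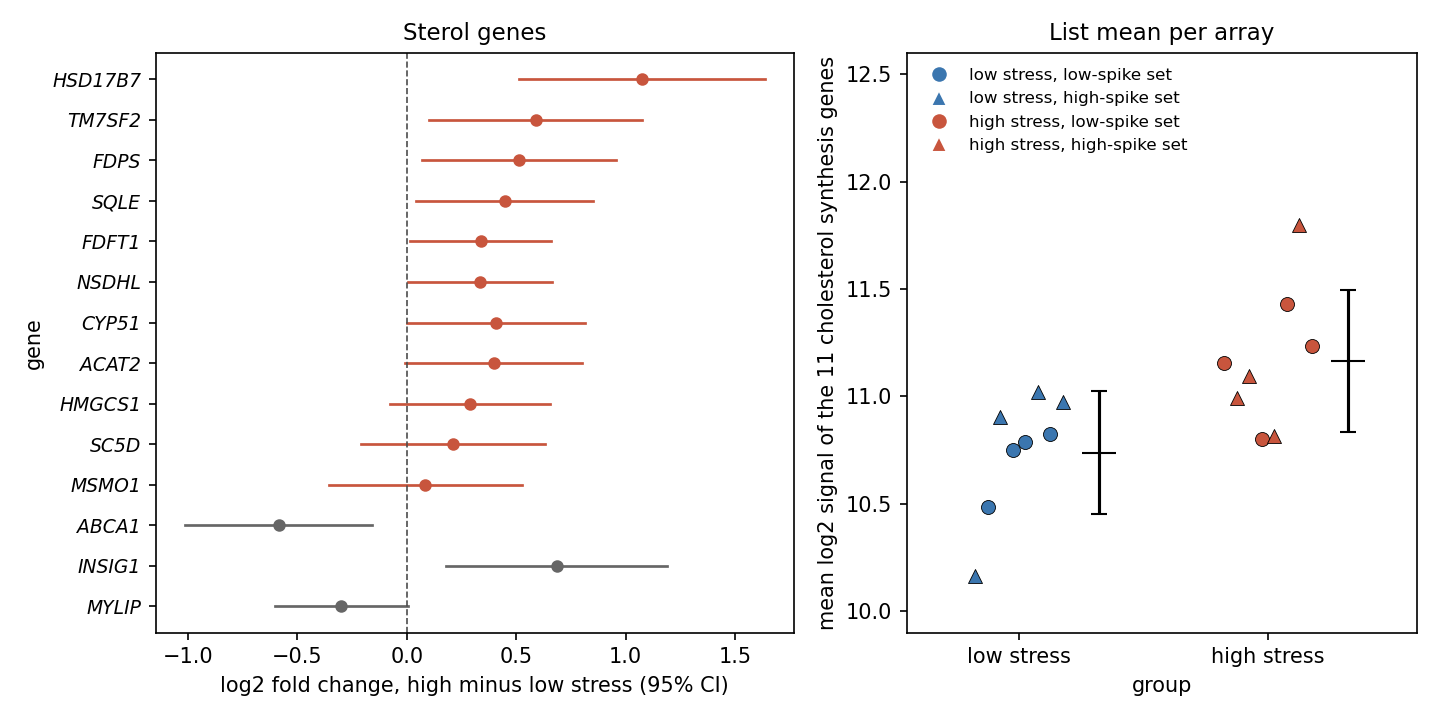
The left panel gives the log2 fold change, high minus low stress, with its 95% confidence interval for the 11 measured cholesterol synthesis genes (red) and 3 genes of the cholesterol uptake, storage and transport list (grey). The right panel gives the mean log2 signal of the 11 genes per array, with shape for the spike-in set and the mean ± SD of each group of 8 beside the points; the groups average 11.17 and 10.74.

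Genes that regulate cellular sterol did not move as a list. Of 19 measured genes of cholesterol uptake, storage and transport, 8 were higher and 11 lower, and the list did not pass camera (adjusted p = 0.564). Its 3 genes with the smallest p went in different directions, and none passed. INSIG1, which holds back sterol regulation and is itself induced by it, had a log2 fold change of 0.68 (SE 0.24). ABCA1, the cholesterol export pump, had -0.59 (SE 0.20), and MYLIP, a ubiquitin ligase, had -0.30 (SE 0.14). Of 16 genes of fatty acid synthesis 11 were higher (adjusted p = 0.175), with SCD, the stearoyl-CoA desaturase, at 0.41 (SE 0.16).

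A further 3 lists passed camera, each with a small shift towards high stress. Of 29 genes of the proteasome, the protein-degrading complex, 25 were higher, with a median log2 fold change of 0.10 (adjusted p = 0.000816, and 0.796 with an estimated correlation). PSMB6 had 0.28 (SE 0.13), PSMB3 0.25 (SE 0.14) and PSMD4 0.17 (SE 0.09). Of 50 genes of oxidative phosphorylation, the respiratory chain and ATP synthase, 46 were higher, with a median of 0.07 (adjusted p = 0.00193, and 0.796 with an estimated correlation). ATP5G1 of the ATP synthase had 0.25 (SE 0.13) and NDUFB2 of complex I 0.21 (SE 0.11), while NDUFS1 of the same complex had -0.15 (SE 0.08). Of 19 genes of the endoplasmic reticulum stress response 15 were higher, with a median of 0.11 (adjusted p = 0.00193, and 0.796 with an estimated correlation). Among these DNAJB11, a chaperone of the reticulum, had 0.20 (SE 0.08), the transcription factor ATF4 0.25 (SE 0.13), the chaperone DNAJB9 0.19 (SE 0.10) and the secreted protein MANF 0.31 (SE 0.16). No single gene of the 3 lists passed, over all genes or adjusted over the list alone.

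With the set as a block the adjusted p was 2.19e-05 for the proteasome, 8.35e-05 for oxidative phosphorylation and 0.00122 for the endoplasmic reticulum list. These calls were lost as well with an estimated correlation beside the block (adjusted p = 0.736, 0.766 and 0.721 with an estimated correlation). Within the low-spike and the high-spike set the mean log2 fold changes were 0.09 and 0.09, 0.11 and 0.05, and 0.14 and 0.09, in the same order. The median log2 signal of an array, a sign of how the arrays were scaled, was 7.01 ± 0.11 in high stress and 7.09 ± 0.08 in low stress (SD, n = 8 each; exact two-sided permutation p = 0.156, and 0.0592 within the sets). After quantile normalization without the block none of the 3 lists passed (adjusted p 0.0836, 0.323 and 0.0537). With the set as a block beside it, oxidative phosphorylation again did not pass (adjusted p = 0.315). The proteasome and endoplasmic reticulum lists then passed at the preset correlation. Camera with its preset correlation called a median of 4 lists in 99 other splits of the arrays, against 4 in the real one.

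**Figure D3:**
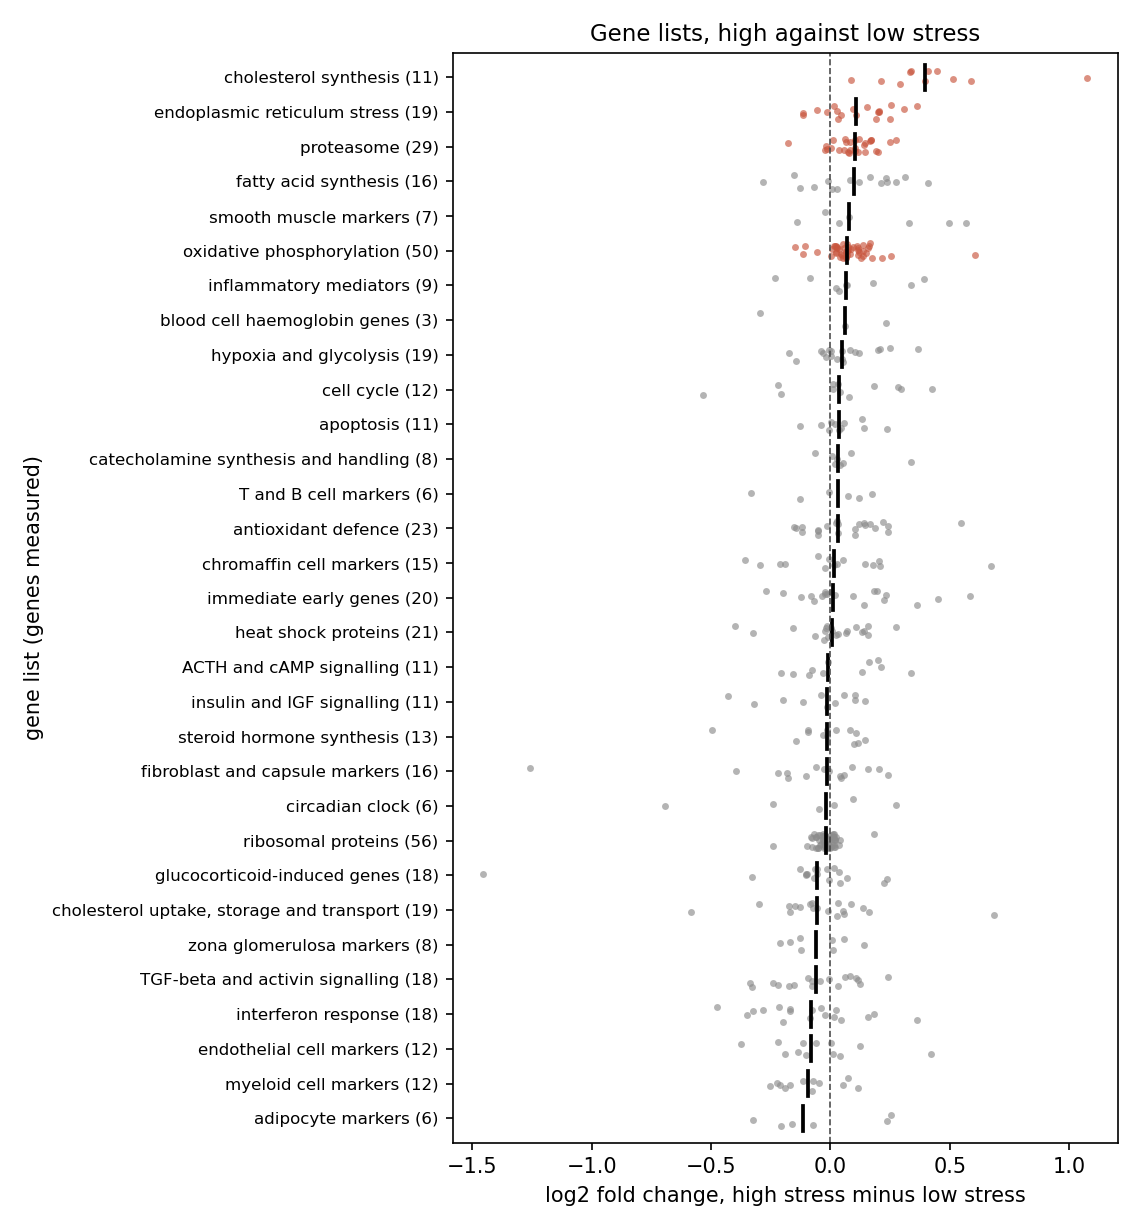
Each point is the log2 fold change of 1 gene, high minus low stress, in the 31 gene lists tested, with the number of genes measured in brackets and a black bar at the list median. The 4 lists in red passed camera at an adjusted p under 0.05 with its preset correlation, and the cholesterol synthesis median of 0.40 lies farthest from 0.

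No probe set passed limma at an adjusted p under 0.05 without the block. At an unadjusted p under 0.05, 460 of 14399 did, 183 higher and 277 lower, where chance alone gives about 720. Quantile normalization turned that split to 240 higher and 185 lower, and centring on the median to 318 higher and 126 lower. With the set as a block 1 probe set passed, that of NPM3, a nucleolar histone chaperone. It averaged 9.11 ± 0.22 in high stress and 8.56 ± 0.22 in low stress on the log2 scale (SD, n = 8 each). That is 1.46-fold higher (95% confidence interval 1.23 to 1.74 without the block). In the fit with the block the log2 fold change was 0.55 (95% confidence interval 0.39 to 0.71). The adjusted p was 0.0316 with the block and 0.999 without it. With the first digit of the animal number as a further block no probe set passed limma (NPM3 adjusted p = 0.182; 913 at an unadjusted p under 0.05). In 8 of 8 high stress animals NPM3 lay above the low stress mean.

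The other genes with the smallest p, none of which passed either fit, included enzymes and regulators of several kinds. On the high stress side were GPX1, the selenium-dependent glutathione peroxidase, at 1.46-fold (log2 fold change 0.55, SE 0.12), and ZDHHC16, a protein acyltransferase. The mean log2 signal of ZDHHC16 in low stress was 5.78, below the filter value of 6.15, so the size of its difference is uncertain. Low stress replicates 3, 4 and 8 lay at 6.88 to 7.12, within the high stress range of 6.27 to 7.50. The other low stress animals lay at 4.77 to 5.55. The log2 difference was 1.37 (SE 0.36), and 1.02 with a pseudocount. FBP1 of gluconeogenesis, the acetoacetyl-CoA thiolase ACAT2 and the alkaline phosphatase ALPL had log2 fold changes of 0.55, 0.58 and 0.69. IDS, CARHSP1, ACOT7, PIR and POP4 lay between 0.33 and 0.53. Another probe set of ACAT2, the brighter one used in the cholesterol list, gave 0.40. In ZDHHC16, CARHSP1, LOC414400 and SMUG1, 1 high stress animal each lay far from the other 7. On the low stress side CRY2, a repressor in the circadian clock, was at 0.619 of its low stress level (log2 fold change -0.69, SE 0.17), below the low stress mean in each of the high stress animals. CYP2E1, a cytochrome P450, had -1.04 (SE 0.33), PAPPA, a protease of IGF-binding proteins, -0.65 (SE 0.20), and the cyclin CCNG2 -0.43 (SE 0.13). RNASE10, ALMS1, CRIM1, SMUG1, CAST, LOC414400, LOC100515551 and LOC100523870 lay between -0.73 and -0.32. The high stress means of PAPPA and RNASE10 were also below the filter value. Adjusted over the list alone, GPX1 passed among 23 genes of antioxidant defence (adjusted p = 0.00627) and CRY2 among 6 of the circadian clock (adjusted p = 0.00309); neither list passed camera (adjusted p = 0.137 and 0.273).

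Genes of steroid hormone synthesis did not differ detectably. Of 13 measured, 6 were higher and 7 lower, with a median log2 fold change of -0.01 (adjusted p = 0.816), and none passed. Camera, which sets the list against the other genes, pointed to higher although the median and the mean of -0.02 were below 0. STAR, which brings cholesterol into the mitochondrion, had a log2 fold change of -0.03 (95% confidence interval -0.23 to 0.17). CYP11A1, which cuts the cholesterol side chain, had 0.03 (-0.17 to 0.22), with 1 low stress animal far below the others. HSD3B1 had -0.09 (-0.31 to 0.12) and CYP17A1 0.10 (-0.26 to 0.45). The list's smallest p values belonged to HSD11B2, which inactivates cortisol, at -0.50 (SE 0.30), and HSD17B12 at 0.14 (SE 0.09). The corticotropin receptor MC2R had -0.08 (-0.52 to 0.37), within a list of ACTH and cAMP signalling of which 5 of 11 genes were higher (adjusted p = 0.736). The lipoprotein receptor SCARB1 had 0.09 (-0.13 to 0.31).

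Genes that respond to stress hormones or to acute stimulation did not pass as lists either. Of 18 glucocorticoid-induced genes 12 were lower (adjusted p = 0.440), among them FKBP5, a chaperone of the glucocorticoid receptor, at -0.33 (95% confidence interval -0.71 to 0.05), and the metallothionein MT1A at -1.45 (SE 0.59). Of 20 immediate early genes 11 were higher (adjusted p = 0.313), with FOS at 0.45 (-0.12 to 1.02) and IER3 at 0.58 (SE 0.28). The mean log2 fold change of the immediate early list was -0.28 within the low-spike set and 0.45 within the high-spike set, and the list passed camera at its preset correlation in opposite directions in these sets (adjusted p = 0.0119 and 1.98e-07). The difference between the sets did not pass an exact permutation test after adjustment (p = 0.0453, adjusted 0.747). Over all arrays the list had an adjusted camera p = 0.796 with an estimated correlation. Opposite shifts offset each other over all arrays, and the estimated correlation was not used within a set. That value therefore does not test the calls within the sets. The heat shock proteins were 12 higher and 9 lower of 21 (adjusted p = 0.451). Catecholamine synthesis and handling had 7 of 8 genes higher (adjusted p = 0.443), with PNMT, which makes adrenaline, at 0.04 (-0.35 to 0.43) and MAOB at 0.34 (SE 0.16). The other lists, for fuel metabolism, growth factors, ribosome, cell cycle, cell death and immunity, had adjusted p of 0.273 or more.

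Some of the genes with the smallest p and of the adrenal genes chosen beforehand had values that differed in sign or by over 2 times between the low-spike and the high-spike set. PIR had 0.30 and 0.69, CCNG2 -0.63 and -0.24, LOC100523870 -1.06 and -0.40, and CYP2E1 -0.66 and -1.42, in that order. FOS had 0.01 and 0.89, FKBP5 -0.45 and -0.21, MC2R -0.30 and 0.15, and PNMT 0.27 and -0.19. STAR had 0.03 and -0.10, CYP11A1 0.10 and -0.05, HSD3B1 -0.03 and -0.16, and SCARB1 0.20 and -0.03. The differences between the sets were not tested for these genes.

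The make-up of the glands, read from the mean signal of markers of 9 cell types, did not differ detectably over all 16 animals. Chromaffin cell markers averaged 10.55 ± 0.27 in low stress and 10.57 ± 0.28 in high stress on the log2 scale (SD, n = 8 each), a difference of 0.02 (exact permutation p = 0.860). The difference was -0.05 for zona glomerulosa markers, -0.05 for endothelial cell markers, -0.10 for fibroblast and capsule markers and 0.19 for smooth muscle markers (exact permutation p = 0.692, 0.367, 0.387 and 0.222). It was -0.09 for myeloid cell markers, -0.02 for T and B cell markers, -0.05 for adipocyte markers and -0.00 for haemoglobin genes of blood cells, and each of the 9 adjusted p was 0.997. Camera at its preset correlation called smooth muscle markers within the high-spike set (adjusted p = 2.80e-05; mean log2 fold change 0.42, against -0.03 in the low-spike set) and with the mean of a gene's probe sets (adjusted p = 0.0378). It called zona glomerulosa markers lower within the low-spike set (adjusted p = 0.0285; mean -0.30, against 0.20 in the high-spike set). Exact permutation tests of the difference between the sets gave p = 0.0935 and 0.0494, both 0.747 adjusted. Over all arrays both lists had an adjusted camera p = 0.796 with an estimated correlation. The estimated correlation was not used within a set, so that value does not test the calls within the sets. In the smooth muscle list TAGLN had a log2 fold change of 0.50 (SE 0.20) and TPM2 0.57 (SE 0.25), and among chromaffin markers the neuropeptide gene GAL had 0.67 (SE 0.29). None of these genes passed over all genes; TAGLN and TPM2 passed only adjusted over the list alone with the set as a block (adjusted p = 0.0204 and 0.0213).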

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

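The tests of a larger share of cortex and of the origin of the 2 spike-in sets were chosen only after the result was seen, as were all tests that use these sets.

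Cholesterol synthesis genes had higher values in high stress glands, but the call was lost with an estimated correlation (adjusted p = 0.389) and the exact permutation p of the list mean was 0.304 adjusted over the lists. With the ratio of 3' to 5' actin signal as a covariate and the set as a block, the mean log2 fold change of the list was 0.448, against 0.426 without the covariate, which argues against RNA quality, as far as actin measures it, as the whole cause. The smaller of the mean log2 fold changes in the 2 spike-in sets was 0.408, in the high-spike set. That difference leaned on low stress replicate 1 at 10.16 and high stress replicate 7 at 11.80. The other animals of the set lay at 10.90 to 11.02 in low stress and at 10.81 to 11.09 in high stress. The test therefore could not show that both sets carried the difference. The list median lay at percentile 100 of 10000 random lists matched on signal, which argues against a signal-dependent trend. A larger share of cortex in the sample would have raised steroid hormone synthesis genes as well, but the upper 95% limit of that list's mean was 0.0419. A difference between the stress groups stays a hypothesis, and chance stays open.

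Most proteasome and oxidative phosphorylation genes (25 of 29 and 46 of 50) had slightly higher values in high stress glands, but no gene passed. Both calls were lost with an estimated correlation (adjusted p = 0.796 for each). The exact permutation p of the list means was 0.184 and 0.349. With labels exchanged only within the spike-in sets it was 0.0220 and 0.123, or 0.228 and 0.635 adjusted over the 31 lists. The joint median of both lists lay at percentile 99.98 of 10000 random lists matched on signal. Their joint mean log2 fold change was 0.0949 with the actin covariate and the set as a block, against 0.0850 without the covariate. The values with the covariate argue against RNA quality, as far as actin measures it, as the whole cause. The percentile argues against a signal-dependent trend only as far as the genes vary independently. Scaling between the arrays stays open. Quantile normalization took the excess of the list median over the median of all genes from 0.10 to 0.04 for the proteasome. For oxidative phosphorylation the excess went from 0.07 to 0.02, and neither list passed camera (adjusted p = 0.0836 and 0.323). With the set as a block as well, the proteasome list passed at the preset correlation and oxidative phosphorylation did not (adjusted p = 0.315). Genes of one complex vary together, which random lists do not take into account, and a biological difference between the groups stays open as well.

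The arrays fell into 2 sets by their spike-in controls. The difference between the numbers of high and low stress arrays within a set was 0, so the stress groups did not make the sets. A labelling batch could account for them, since the smallest difference among the 4 poly-A controls added to the RNA was 0.998 log2 units, while the hybridization controls added later differed by at most 0.418. Each hybridization control was lower in the high-spike set, by log2 differences of -0.247 to -0.418 (SE 0.053 to 0.080). That is opposite in direction to the poly-A controls, so the sets differed in the later controls too. The bound written for this test was 1 log2 unit, and 0.998 lies within its own error of that bound, so the test left a labelling batch open. No label names such a batch, and no biological explanation was tested.

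Chance was weighed by refitting 100 splits of the 16 arrays into 8 and 8, the real one included. Without a block the real count past the adjusted threshold was 0, which all 100 splits reach by construction (highest other 287), so that count tests nothing. Of the same splits, 49 gave at least 460 at an unadjusted p under 0.05 (highest other 4037), and 54 called at least 4 gene lists (highest other 10). Neither of the latter counts excluded chance. The highest of these splits put 7 of the 8 arrays of one spike-in set on one side, and 18 other splits gave over 2 times the real count, which points to the structure of the arrays. In 100 splits within the sets, with the set as a block, 3 gave at least 1 probe set past the adjusted threshold (highest other 1). That count was thus uncommon in this fit. Other splits reached it too, and several counts were weighed without adjustment, so chance was not excluded for it. The count was 0 with the digit of the animal number as a further block, a fit for which no splits were drawn. With the same block 14 splits gave at least 919 at an unadjusted p under 0.05 (highest other 1738) and 62 called at least 4 lists (highest other 13), so chance was not excluded for these. Of the other 99 splits, 97 without the block and 96 with it called at least 1 list. The cholesterol synthesis list was called as strongly in 5 of 100 splits without the block and in 1 of 100 with it, the real split included in both.

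Among 136 groups of 8 values, 8 held 1 animal far from the others, where chance gives about 6.80. Low stress replicate 3 lay low in the mean log2 signal of cholesterol uptake, storage and transport genes at 9.97, where the other 7 averaged 10.26, and in that of endothelial cell markers at 8.70 against 8.94. The same animal had the lowest CYP11A1 at 13.97 against 14.46. Low stress replicate 4 lay high in the heat shock proteins at 11.53 against 11.39. ZDHHC16 was low in high stress replicate 8 at 6.27 against 7.28, and SMUG1 was low in high stress replicate 2 at 7.91 against 8.32. CARHSP1 was high in high stress replicate 7 at 10.23 against 9.38, and LOC414400 was high in high stress replicate 1 at 8.56 against 7.17.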

How the results depend on the processing

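The fits that use the spike-in sets or the actin covariate, and the exact permutation of list means, were tests chosen after the data were seen. Signal near background limits the dim probe sets. The labels give the groups no shared replicate numbers, but each first digit of the animal number held 1 high and 1 low stress animal in each spike-in set. With that digit as a block, alone or with the set, 0 probe sets passed limma (426 and 913 at an unadjusted p under 0.05).

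The count of probe sets past an adjusted p under 0.05 was 0 without a block and 1 with the spike-in set block, 1 with the block and quantile normalization, and 1 with the block and the actin covariate, each time NPM3, but 0 with the set and digit blocks (adjusted p = 0.182). It was 1 at an adjusted p under 0.25, a probe set without a gene name (adjusted p = 0.139, and 0.0604 with the set block) and not NPM3, 460 at an unadjusted p under 0.05, and 0 to 0 when each animal was left out. The count of 460 became 906 with no filter, 289 with the filter at the 60th percentile, 786 with array weights, 919 with the set block, 913 with set and digit blocks, 842 with the set block and quantile normalization, 1198 with the set block and actin covariate, and 1063 within the low-spike set. Leaving out each animal gave 363 to 681.

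The number of lists past camera, 4 without a block, was 1 after quantile normalization, 7 within the low-spike set, 0 with an estimated correlation, 0 with fry, 0 for each of these with the set block, 0 for the exact permutation of list means and 0 for that within the sets. It was 3 without high stress replicate 4 and 7 without high stress replicate 6, the full range. With an estimated correlation the adjusted p was 0.389 for cholesterol synthesis and 0.796 for the endoplasmic reticulum, oxidative phosphorylation and proteasome lists, and with the set block as well 0.721, 0.721, 0.766 and 0.736. With fry it was 0.586, 0.608, 0.857 and 0.857, and with the set block and fry 0.233, 0.233, 0.508 and 0.233. After quantile normalization it was 0.0537 for the endoplasmic reticulum list and 0.0836 for the proteasome (both passed with the set block at preset correlation). For oxidative phosphorylation it was 0.323 (0.315 with the set block). Within the high-spike set it was 0.0655 for the endoplasmic reticulum list and 0.191 for oxidative phosphorylation, with fewer animals. Leaving out each animal gave 3.09e-12 to 1.01e-06 for cholesterol synthesis, 0.00136 to 0.0188 for the endoplasmic reticulum list, 2.46e-05 to 0.0743 for oxidative phosphorylation (lost without high stress replicate 4) and 5.35e-05 to 0.0258 for the proteasome. The immediate early genes, not called over all arrays, were lower within the low-spike set (adjusted p = 0.0119) and higher within the high-spike set (1.98e-07) at the preset correlation (adjusted p = 0.796 with an estimated correlation over all arrays). Further lists passed when 1 animal was left out: fatty acid synthesis without low stress replicate 8 (adjusted p = 0.0467), immediate early genes without low stress replicate 1 (0.0197) or 2 (0.0158) or high stress replicate 6 (0.0295), antioxidant defence without high stress replicate 3 (0.0382) or 5 (0.0393), myeloid markers without high stress replicate 6 (0.0466), smooth muscle markers without low stress replicate 7 (0.0154) and ribosomal proteins without low stress replicate 3 (0.000688), high stress replicate 1 (0.0366) or 6 (0.0258). Apart from sample number, filter size and the correlation used, the cause was not tested. Median, mean and camera also differed in sign for ACTH signalling, T and B cell, haemoglobin and chromaffin lists, none with a call. No cell type list passed the exact permutation test in any alternative. Among 1078 alternative values of named genes, 18 changed sign, all in genes without a call.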

Other observations

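The lists of selenoproteins and of sterol-sensor targets, and the relation of ABCA1 to cholesterol synthesis, were tests chosen only after the result that prompted them was seen.

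Immediate early genes, which respond within minutes to stimulation, varied between animals more than between the stress groups. Their mean log2 signal was 10.20 and 10.33 in low stress replicates 1 and 2 and 10.47 in high stress replicate 7, and at most 9.93 in each of the other 13 animals. The mean of the cholesterol synthesis list was 10.16 and 10.49 in these low stress animals, the lowest of the 16, but 11.80 in high stress replicate 7, the highest.

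Immune and signalling genes did not pass as lists. Of 18 interferon response genes 12 were lower in high stress (adjusted p = 0.518), among them GBP2 at a log2 fold change of -0.35 (SE 0.19) and IFIT2 at -0.47 (SE 0.26), while the antigen transporter TAP1 had 0.36 (SE 0.13); none of the 3 passed. Of 9 inflammatory mediators 7 were higher (adjusted p = 0.366), and of 56 ribosomal protein genes 38 were lower (adjusted p = 0.443). Camera at its preset correlation called the ribosomal list lower within the high-spike set (adjusted p = 0.0207) and antioxidant defence higher within the low-spike set (0.0119). Over all arrays their adjusted p was 0.899 and 0.796 with an estimated correlation, which was not used within a set and does not test these calls. Of 11 genes of insulin and IGF signalling 6 were lower (adjusted p = 0.451); adjusted over the list alone, IGFBP5 passed only with the set as a block (adjusted p = 0.0427).

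ABCA1 was lower where cholesterol synthesis was higher across the 16 animals, after the mean of each group within each spike-in set was removed (Pearson r = -0.556, permutation p = 0.0514; Spearman rho = -0.432, permutation p = 0.153; 1 relation tested). The r was -0.245 without the 2 animals farthest from the median, so the relation rests on those animals. It was -0.798 within low stress and -0.422 within high stress, and 0.160 within the low-spike set and -0.939 within the high-spike set. A shared variation between animals could not be told from chance.

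GPX1 and SELENOW, both selenoproteins, prompted the hypothesis that selenoprotein genes as a family were higher. The 12 others measured gave a camera p of 0.104 with the set as a block, with 9 higher and 3 lower, so the family did not pass without the genes that prompted it. ABCA1 and MYLIP prompted the hypothesis that targets of the sterol-sensing LXR receptors were lower. The 7 others gave a camera p of 0.436, with 4 higher and 3 lower, and so did not pass either.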
